A study of Mus musculus with 4 samples.

How the data were processed

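Cerebral cortex of 4 mice was profiled by single-cell RNA sequencing, with 1 animal labelled wild type and 1 labelled Tsku knockout in the embryo (E14.5) and 1 of each on the day of birth (P0), per the labels' protocols. Tsku encodes Tsukushi, a secreted small leucine-rich proteoglycan. Tissue was dissociated with trypsin, and 15000 cells of each sample were coupled to the capture beads of the Asteria kit before lysis, reverse transcription and amplification, per the labels' protocols. The libraries were sequenced on an Illumina instrument, per the labels' protocols. The deposited values are counts, given as whole numbers per gene and cell barcode with no scaling, for 57126 features in each library. The build GRCm39 and the tools FastQC 0.12.1, Seurat 5 and R 4.3.2 are named in the submitters' processing notes without a role. The aligner, the counting program, the annotation release and the filter that chose the barcodes are not given in the sources used here, and neither is whether reads were collapsed to molecules. Counts are treated here as independent, so every interval and limit covers counting error only.

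The files hold 622 barcodes for E14.5 wild type, 4119 for the library labelled E14.5 knockout, 1073 for P0 wild type and 1456 for P0 knockout. Barcodes with at least 500 counts, at least 300 genes and at most 10% mitochondrial counts were kept, which left 620, 4107, 1047 and 1436. Doublets were called in each library with Scrublet through scanpy 1.11.5 at an expected rate of 5%, and 2, 0, 3 and 6 barcodes were removed. A caller that marks under 0.5% of each library did not separate doublets in practice, so doublets remain among the cells, and removal of the 5% of cells with the highest scores was tried as an alternative. The analysed cells numbered 618, 4107, 1044 and 1430, with 5584291, 14404051, 6025289 and 8812049 counts. Median counts per analysed cell were 7316, 2829, 4806.5 and 5059, and median genes per cell were 3041.5, 1702, 2413.5 and 2529. The cells of the library labelled E14.5 knockout are thus the most numerous and the shallowest.

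Cells of each age were clustered over both libraries with scanpy 1.11.5 in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without Tsku and without sex-linked, mitochondrial and ribosomal protein genes, and 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9, resolution 1, seed 0) were used. Clusters were named from marker lists fixed before the data were examined. For every marker the mean log value per cluster was standardised over the clusters of an age, and a cluster took the class with the highest mean over the lists of that class. A cluster stayed unnamed if the next class came within 0.25, unless at least 3 of its 10 leading genes were markers of the best class and outnumbered those of any other. It also stayed unnamed if fewer than 3 markers were raised by 0.5 or more and detected in at least 10% of its cells, if its leading genes held more markers of another class, or if its cells were very shallow and led by no marker of the class. Leading genes were ranked by fold over all other cells, with 0.05 added to both means. These scoring rules, and the exception for 3 leading markers, were set after the clusters had been seen. They left 2.10% of E14.5 wild-type cells, 2.43% of cells of the library labelled E14.5 knockout, 7.95% of P0 wild-type cells and 17.5% of P0 knockout cells unnamed. Names carry the suffix "-like", since no annotation of the cells is given in the sources used here, and a class may differ from the one the study used.

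Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, sums of counts carry exact Poisson intervals, and ratios of 2 sums carry intervals from the conditional binomial distribution. For each class with at least 50 cells in both libraries, counts were summed over cells and scaled to a common total per sum (CPM), and the log2 ratio of knockout or knockout label over wild type was taken for genes with at least 30 counts over both sums. A sum of 0 was set to a floor of 3 counts and its ratio is given against that floor. No group has replicates, so no test across animals was made and no p-value is given. The median log2 ratio of each fixed list with at least 5 measured members was placed as a percentile among 10000 random lists of equal size matched on mean expression in 20 bins, which describes these libraries and does not compare genotypes. The fixed lists were 21 of cell type markers and 24 of pathways and gene families. They gave 129 medians at E14.5, 130 at P0 and 108 between the ages in wild type, and the lists described were picked from these after the medians had been seen. Ratios are relative to the class sum, and the median gene lay within 0.1 of 0 on the log2 scale in every class but E14.5 intermediate-progenitor-like cells, where it lay at 0.10. Under TMM scaling (trimmed mean of M values, written in Python here) ratios shifted by at most 0.07 within an age. Between the ages the shift was 0.11 in intermediate-progenitor-like cells of wild type, and 0.11, 0.14 and 0.11 in projection-neuron-like, intermediate-progenitor-like and inhibitory-neuron-like cells of the knockout labels. The median gene in E14.5 radial-glia-like and astrocyte-like cells lay at 0.13 under TMM.

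Genes are named by a rule fixed before the data were examined. Tsku comes first. In each comparison of genotypes, the 4 classes with the most cells in the smaller library each give the 4 highest and 4 lowest genes among those at 100 CPM or more in either library. Members of the mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked lists are left to those lists. Erdr1y is on none of them and so is named. Up to 10 genes that go the same way by at least 1 log2 unit in every compared class are added, and each described list gives 2 to 4 of its most abundant members. Between the ages in wild type the 5 highest and 5 lowest genes of each class are taken. Other genes named were picked after their values had been seen, which is said where they appear. A few genes that the rule names, and tests that rest on such a gene, are not reported here. Gene names come from the feature tables, and several features have no symbol beyond their Ensembl identifier. Annotated transcript lengths and the neighbours of Tsku come from GENCODE M21 on GRCm38, another assembly than the counts use, so no coordinates are given.

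Counts over the S phase and G2M phase lists were read from cells thinned to 1500 counts each, a number chosen after the depths had been seen, with shallower cells left out. The measure set beforehand, a cell with 2 or more such counts, held for 92.3% to 99.9% of cells in every class and so separates nothing. A threshold of 15 counts was added after that had been seen.

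The steps were tested on simulated data drawn from the summed counts of projection-neuron-like cells with 200 genes changed by known folds. Draws were Poisson, as the intervals assume, so coverage near 95% was built in. They held no further spread between cells, and smaller classes were not simulated. For E14.5, over 10676 genes, 95.9% of unchanged genes had the true ratio inside the interval, and the interval lay on the true side of 0 for 68.8%, 93.7% and 100% of genes changed 1.5-fold, 2-fold and 4-fold. For P0, over 9748 genes, the corresponding values were 96.0%, 65.7%, 87.5% and 100%. Unchanged lists of 20 genes fell outside the central 95% of random lists in 3.5% of draws for E14.5 and 5% for P0, and lists raised 1.5-fold passed it in 100% of draws for both. Unchanged lists came from the same pool as the random lists, and every member of a raised list was shifted alike. Lists whose members vary together were not simulated. With 20 abundant genes raised, the TMM offset was -0.86 against a true -0.84 for E14.5 and -0.72 against -0.73 for P0.

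The alternatives set beforehand were all deposited barcodes, a stricter filter of 1000 genes and 5% mitochondrial counts, doublets kept, resolutions of 0.5 and 2, all 4 libraries clustered together, each library clustered alone, thinning before clustering, and classes from each cell's own marker score. For ratios they were TMM scaling, sums without mitochondrial, ribosomal protein and haemoglobin genes, means over cells scaled to 10000, thinned sums, and count minimums of 100 or none. Those added after the data had been seen were removal of the top 5% of doublet scores, unnamed clusters placed in their best class, P0 shares without clusters found in 1 library, shares among radial glia, intermediate progenitors and projection neurons alone, and the threshold of 15 cycle counts.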

Results

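Gene expression was measured in single cells of the cerebral cortex in 4 libraries, each from 1 mouse: wild type and a library labelled Tsku knockout at E14.5, and wild type and Tsku knockout at P0. There are no replicates, so each comparison is between 2 animals and its intervals cover counting error only. The deposited libraries held 5607941 counts for E14.5 wild type, 14423600 for the library labelled E14.5 knockout, 6136897 for P0 wild type and 8959784 for P0 knockout. After filtering, 618, 4107, 1044 and 1430 cells entered the comparisons, at median depths of 7316, 2829, 4806.5 and 5059 counts per cell. The 15000 cells put into each reaction thus gave unequal numbers of barcodes, and the depth gap at E14.5 stands beside every share and ratio at that age.

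Tsku, the targeted gene, was counted in 3 of the 4 libraries. The P0 knockout library held 0 counts in 1430 cells, where 61.4 would be expected at the level of P0 wild type. Against a floor of 3 counts Tsku was 20.5-fold lower, and the 95% interval of its ratio to wild type reached up to 0.063. The P0 wild-type library held 42 counts, or 6.97 CPM, counts scaled to a common total (95% interval 5.02 to 9.42). The library labelled E14.5 knockout held 74 counts, or 5.14 CPM (4.03 to 6.45), and E14.5 wild type held 52, or 9.31 CPM (6.95 to 12.2). Tsku in the library labelled E14.5 knockout was therefore at 0.552 times the wild-type level (0.382 to 0.802), and these counts contradict the label. Which part of the gene the knockout allele lacks is not given in the sources used here, but the counted part was absent at P0.

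The Tsku counts of the library labelled E14.5 knockout lay mostly in the classes that held them in wild type. Projection-neuron-like cells had 39 counts in 1419 cells, or 7.49 CPM (5.33 to 10.2), against 10.3 (6.60 to 15.3) in wild type. Radial-glia-like cells had 12 counts, or 5.18 CPM (2.68 to 9.05), against 18.2 (10.2 to 30.1) in wild type. Inhibitory-neuron-like cells had 7 counts in 942 cells, or 2.60 CPM (1.05 to 5.36), and 0 counts in the 128 cells of wild type, which allows up to 4.00. Median depths in the library labelled E14.5 knockout were 3000 counts in projection-neuron-like and 2362.5 in inhibitory-neuron-like cells, and in wild type they were 7466 and 6048. In P0 wild type the highest level was in 6 meningeal-fibroblast-like cells, with 132 CPM (48.6 to 288).

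The 2 E14.5 animals also differed in sex. The library labelled E14.5 knockout held 6719 counts of Xist, the RNA of the inactive X chromosome, and 1 count of Y-linked Ddx3y among all deposited barcodes. E14.5 wild type held 3 counts of Xist and 496 of Ddx3y. Both P0 libraries held 1 Xist count, with 670 counts of Ddx3y in wild type and 1190 in the knockout. Sex and genotype label cannot be separated at E14.5.

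**Figure D1:**
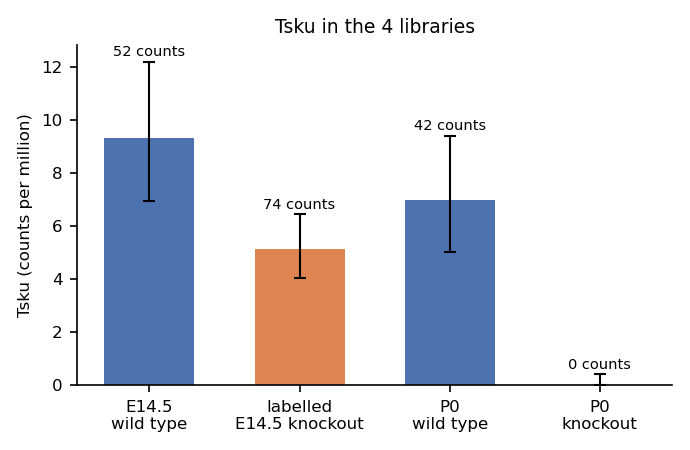
Tsku in the 4 libraries, in CPM over all analysed cells (y axis), with 1 bar per library, exact Poisson 95% intervals as lines and the number of counts above each bar. The library labelled E14.5 knockout stands at 5.14, between 0 in the P0 knockout and 9.31 in E14.5 wild type.

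The series asks how loss of Tsku shifts the balance between neurons and glia in the developing cortex, and class shares are the most direct readout. At E14.5, projection-neuron-like cells made up 41.4% (37.5 to 45.4) of wild-type cells and 34.6% (33.1 to 36.0) of the library labelled E14.5 knockout, a log2 ratio of -0.26 (-0.45 to -0.06), which was -0.52 with all deposited barcodes. Radial-glia-like and astrocyte-like cells made up 13.3% (10.7 to 16.2) and 16.7% (15.6 to 17.9), with a log2 ratio of 0.33 (-0.00 to 0.68). Intermediate-progenitor-like cells, the dividing daughters of radial glia, made up 9.22% and 10.6%, and inhibitory-neuron-like cells 20.7% and 22.9%, and both ratios had intervals that held 0. Among radial glia, intermediate progenitors and projection neurons alone, the progenitor classes together made up 35.2% (30.5 to 40.1) of wild-type cells and 44.1% (42.2 to 46.1) of the library labelled E14.5 knockout. Since Tsku contradicts that label, these directions are between 2 embryos and not between known genotypes. When each library was clustered alone, the log2 ratio was 2.06 for radial-glia-like and 1.40 for inhibitory-neuron-like cells. With 4 libraries together the inhibitory ratio was -0.063, and over all alternatives the intermediate progenitor ratio lay between 0.034 and 0.47.

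Within projection-neuron-like cells at E14.5, markers of deep layer neurons were higher and markers of upper layer neurons lower in the library labelled E14.5 knockout. Of 13 measured deep layer markers 11 lay above 0, with a median log2 ratio of 0.60, above all of 10000 random lists, and among the most abundant were Bcl11b (0.59, interval 0.53 to 0.64), which marks subcerebral neurons, Sox5 (1.12, 1.03 to 1.20), Fezf2 (0.31, 0.19 to 0.44) and Tbr1 (0.60, 0.47 to 0.74). Of 13 upper layer markers 12 lay below 0, with a median of -0.42 at the 0.02th percentile, and examples were Plxna4 (-0.24, -0.34 to -0.14) and Pou3f2 (-1.20, -1.32 to -1.07). The clusters of the class were held in unequal shares. Cluster 10, led by Cntn2, Sox5 and Bhlhe22, made up 5.55% of the library labelled E14.5 knockout and 1.13% of wild type. Cluster 0, with Inhba and Cdh12 among its leading genes and its best score for upper layer markers, made up 4.21% and 9.55%, and cluster 3, led by Bhlhe22, Sema3c and Nr4a3, 2.58% and 8.09%. Cluster 4, whose best score was for deep layer markers, made up 7.96% and 6.63%, with a ratio whose interval held 0, and cluster 12 made up 9.50% and 10.2%. Immediate early genes had a median of -0.39 with 8 of 12 members below 0, including Egr1 (-0.92, -1.06 to -0.77) and Jun (-0.39, -0.58 to -0.21). The 4 highest genes were Cdh11 (1.31), a cadherin, Pfn1 (1.25), a regulator of actin, Rnd3 (1.20), a small GTPase, and Ttr (1.19), a choroid plexus transcript. The 4 lowest were Erdr1y (-2.70), a gene with a near-identical X-linked copy, of uncertain counts in animals of different sex, ENSMUSG00000121500 (-2.45), Atp5me (-2.04) and Ndufb1 (-1.64), the last 2 subunits of mitochondrial ATP synthase and complex I.

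Radial-glia-like and astrocyte-like cells at E14.5 had more cell cycle and neurogenic transcripts in the library labelled E14.5 knockout, whose Tsku counts contradict the label. Most but not all measured astrocyte markers were lower there. The G2M list had 50 of 52 members above 0 and a median of 0.97 that was 0.62 after thinning, and the S phase list 39 of 42 and a median of 0.64, each above all random lists, with Top2a at 0.69 (0.56 to 0.82), Mki67 at 0.69 (0.55 to 0.83) and Pcna at 0.96 (0.82 to 1.11). Cluster 16, the cycling radial glia led by Cenpf and Mki67, held 223 of the 685 cells in that library and 17 of the 82 in wild type. In cells thinned to 1500 counts, 71.9% (68.3 to 75.2) of 668 cells had 15 or more counts over both cycle lists, against 50% (38.7 to 61.3) of 82 wild-type cells, with 17 and 0 shallower cells left out. Projection-neuron-like cells, which should not cycle, gave 0.581% and 0.392% in the same measure, and the unthinned shares in radial glia were 85.3% and 95.1% at median depths of 2841 and 7740. Proneural and neurogenic factors had 12 of 15 members above 0 and a median of 0.59, with Sox11 at 0.60 (0.50 to 0.69) and Btg1 at 0.93 (0.70 to 1.16), but the pan projection neuron list rose in this class too, to 376 CPM against 125. Astrocyte markers had 7 of 9 below 0 and a median of -1.29, below all random lists, with Apoe at -3.62 (-3.97 to -3.28), while abundant Aldoc stood at -0.07 (-0.25 to 0.12) and Gja1 at 0.03 (-0.33 to 0.40). Apoe was also among the 10 leading genes of microglia-like cluster 2 at E14.5, so its ratio need not speak for astrocyte-like cells. Gliogenic factors had 12 of 14 below 0 and a median of -0.24, with Zbtb20 at -0.64 (-0.75 to -0.53) and Nfia at -0.41 (-0.53 to -0.29), and FGF and ERK pathway genes had 11 of 15 below 0 and a median of -0.45, with Fgfr1 at -0.91 and Fgfr3 at 0.90.

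Several leading genes of this class had their counts concentrated in few cells or are known from other classes. The 4 lowest were Lgr6 (-8.06), with 1 count against 95, Mia (-6.84), Bc1 (-5.28) and Fgf17 (-5.21), and 1 wild-type cell held 49.5% of the Lgr6, 50% of the Mia and 53.3% of the Fgf17 counts. The 4 highest were Neurod6 (3.25), a factor of projection neurons, Ttr (2.95), of which 1 cell held 32.5%, Esco2 (1.92), needed for sister chromatid cohesion, and Stmn2 (1.89), a neuronal microtubule regulator. The pan projection neuron list had a median of 1.34 in this class, with 6 of 6 members above 0, and of 1.63 in inhibitory-neuron-like cells, with 5 of 6 above 0, so transcripts of projection neurons were higher in classes that should lack them. Haemoglobin transcripts, which belong to erythroid cells and share reads among their copies, were higher in all 4 compared classes of that library, with medians of 1.64 in projection-neuron-like and 1.39 in radial-glia-like cells.

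In inhibitory-neuron-like cells at E14.5 the library labelled E14.5 knockout had lower immediate early genes, with a median of -0.62 over 10 members, among them Egr1 (-0.98, -1.13 to -0.83) and Fos (-1.12, -1.44 to -0.79), and a lower S phase list, with 33 of 40 members below 0 and a median of -0.33, and the summed list stood at 2671 CPM against 3073 in wild type with 1500 counts per cell and at 2569 against 2708 with 750. The summed G2M list went the other way, at 8734 CPM against 7870 in wild type with 1500 counts per cell and 8519.5 against 7614.6 with 750. Cholesterol synthesis genes had 13 of 16 members above 0 and a median of 0.34. Its highest genes were Wdfy1 (2.57), Ppp2r2b (1.32) and the zinc finger factors Zic4 (1.29) and Zic1 (1.26). Its lowest were ENSMUSG00000121500 (-2.64), Erdr1y (-2.61), Atp5me (-2.52) and Ndufb1 (-1.67). Clusters 7 and 23 held 160 and 75 of the 942 cells in that library and 11 and 4 of the 128 in wild type. In intermediate-progenitor-like cells, deep layer markers had 9 of 9 members above 0 and a median of 0.60, with Bcl11b at 1.28 (0.99 to 1.59), but the pan projection neuron list was higher there too, with a median of 0.72 and 5 of 6 above 0. The G2M list had 36 of 52 members below 0 and a median of -0.24, but at equal depth the summed list showed no clear fall, at 7994 CPM against 8281 in wild type with 1500 counts per cell and 7841 against 7626 with 750. The highest genes there were Gm56862 (1.85), Meg3 (1.82), the Notch ligand Dll1 (1.76) and Igf2bp3 (1.48), an RNA-binding protein. The lowest were ENSMUSG00000121500 (-2.89), Atp5me (-2.54), Ndufb1 (-2.28) and Gm56768 (-2.04). Tsku contradicts the label on which these directions rest.

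Ribosomal protein genes, many of which have near-identical pseudogenes, were lower in all 4 classes of the library labelled E14.5 knockout, with 77 of 104 below 0 and a median of -0.40 (-0.90 with no count filter) in projection-neuron-like cells and 83 of 97 and a median of -0.62 in radial-glia-like cells, though abundant Rps14 stood at 0.35 and 0.12. Among 7302 genes measured in every class, 30 went the same way by at least 1 log2 unit throughout, 8 up and 22 down. The 10 with the largest medians over the classes were Gm15772, with 0 counts in wild type and 400 in that library, AA465934 (2.71), ENSMUSG00000121307 (2.63), Wdfy1 (2.15), ENSMUSG00000121500 (-2.59), Gm36220 (-2.56), Atp5me (-2.53), Erdr1y (-2.43), ENSMUSG00000121655 (-2.10) and Gm56768 (-1.88). Against the floor of 3 counts Gm15772 was 21.8-fold higher in projection-neuron-like cells. Over all cells Wdfy1 stood at 20.2 CPM in E14.5 wild type and at 80.5, 94.4 and 101 in the other 3 libraries, so E14.5 wild type alone stood apart. Gm15772 had 3 counts in P0 wild type and 0 in the P0 knockout, so there the library labelled E14.5 knockout alone did. ENSMUSG00000121307 in radial-glia-like cells went from 2.57 to -0.15 when cells were thinned.

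At P0, where Tsku fits the labels, the knockout library had a larger share of oligodendrocyte-lineage-like cells and smaller shares of both neuron classes. Oligodendrocyte-lineage-like cells made up 4.98% (3.74 to 6.48) of wild-type and 10.5% (8.95 to 12.2) of knockout cells, which is 2.11-fold (1.53 to 2.95), and cluster 12 alone, led by Pdgfra, Lhfpl3 and Olig1, formed the class. Projection-neuron-like cells made up 37.3% (34.3 to 40.3) and 26.8% (24.5 to 29.2), a log2 ratio of -0.48 (-0.68 to -0.27), and inhibitory-neuron-like cells 13.5% (11.5 to 15.7) and 7.41% (6.11 to 8.89), a ratio of -0.87 (-1.24 to -0.49). Radial-glia-like and astrocyte-like cells made up 19.7% (17.4 to 22.3) and 22.6% (20.4 to 24.8), with a ratio of 0.20 (-0.06 to 0.45), and together with the oligodendrocyte lineage 24.7% (22.1 to 27.4) and 33.1% (30.6 to 35.6). Intermediate-progenitor-like cells made up 11% (9.18 to 13.1) and 7.97% (6.62 to 9.50), but this direction turned with the stricter cell filter (0.15), at resolution 2 (0.83), with 4 libraries clustered together (0.40) and with unnamed clusters placed in their best class (0.012). The class is cluster 2 alone, which scored 1.03 for intermediate progenitors and 0.96 for projection neurons. It has a name only through the exception for 3 leading markers, set after the clusters had been seen. The projection neuron ratio shrank to -0.18 with 4 libraries together and to -0.20 with unnamed clusters placed, and the oligodendrocyte ratio of 1.07 was 0.57, and that of radial-glia-like and astrocyte-like cells 0.95, with each library clustered alone.

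Clusters differed within the P0 classes. Unnamed clusters 14 and 19 held 81 and 65 knockout cells against 1 and 2 wild-type cells, which is 5.66% (4.52 to 6.99) and 4.55% (3.53 to 5.76) of the knockout library and, being almost all from 1 library, cannot be separated from a property of that library. Rules for naming set after the clusters had been seen left clusters 9, 13, 14 and 19 without a name, together 7.95% (6.38 to 9.76) of wild-type and 17.5% (15.5 to 19.6) of knockout cells. Cluster 14 scored highest for projection neurons, at 1.07 against 0.18 for the next class. It stayed unnamed because its leading genes held more markers of another class, so the lower projection neuron share in the knockout rests in part on that rule. Without clusters 14 and 19 in the denominator the log2 ratio was 1.23 for the oligodendrocyte lineage, 0.35 for radial glia and astrocytes, -0.33 for projection neurons and -0.71 for inhibitory neurons. Within inhibitory-neuron-like cells, cluster 4, led by Lhx6 and Maf, made up 5.46% of wild-type and 1.82% of knockout cells, and striatal-type cluster 15, with Bcl11b, Foxp2 and Six3 among its leading genes, 3.35% and 0.979%, while cluster 7, led by Dlx1 and Sp8, made up 4.69% and 4.62%. Within radial-glia-like and astrocyte-like cells, cluster 6, led by Fabp7, Slc1a3 and Sparcl1, made up 6.80% and 11.3%.

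**Figure D2:**
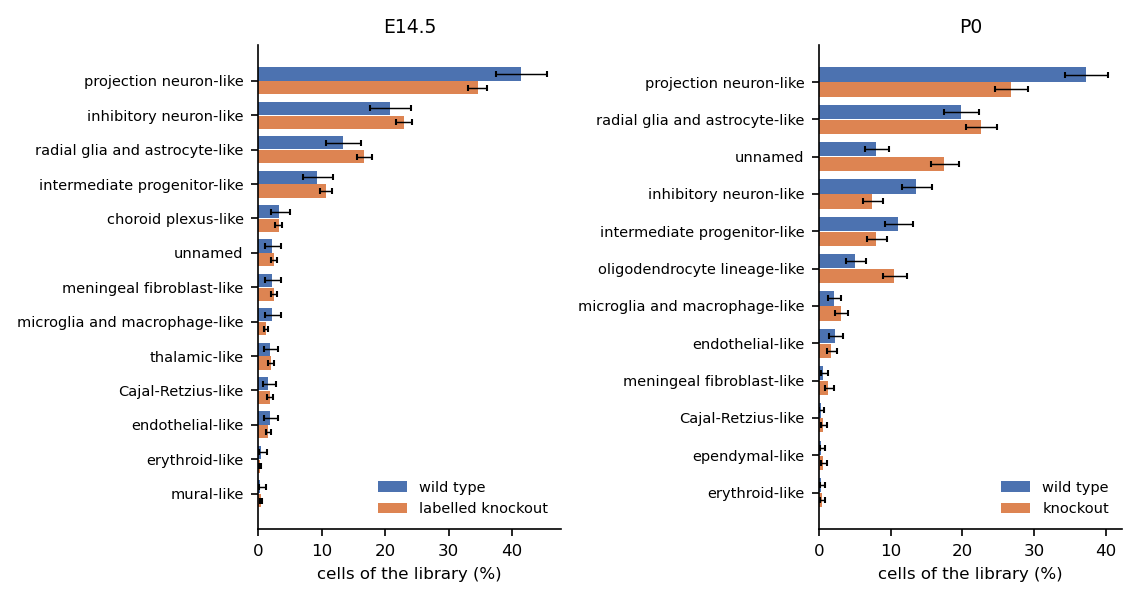
Share of the cells of each library in each class (x axis, percent), at E14.5 on the left and P0 on the right, with bars for wild type and for the knockout label and exact binomial 95% intervals as lines. At P0 the oligodendrocyte-lineage-like share is 4.98% in wild type and 10.5% in the knockout.

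**Figure D3:**
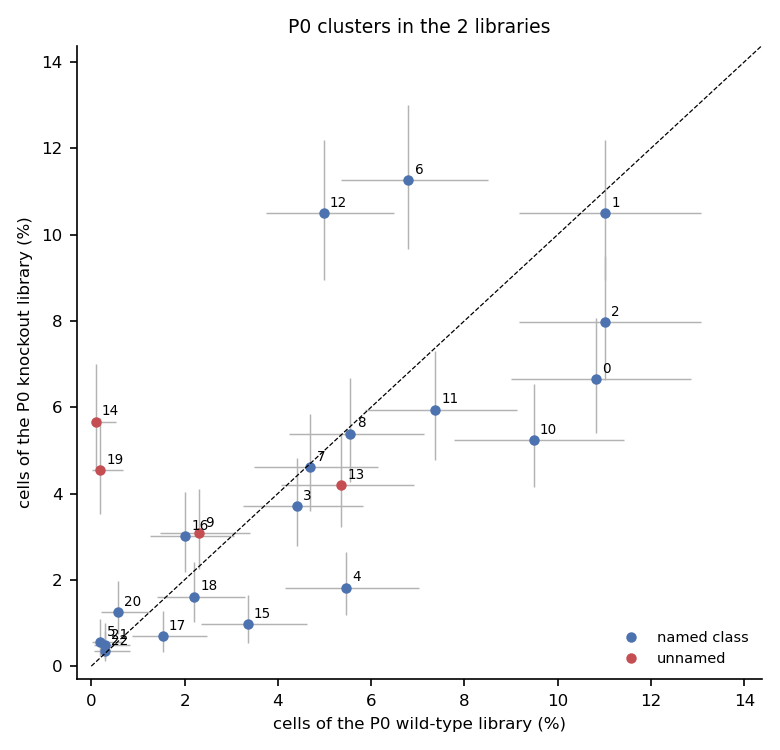
Share of each P0 cluster in the wild-type library (x axis, percent) and in the knockout library (y axis, percent), 1 numbered point per cluster with exact binomial 95% intervals, and a dashed line at equal shares. Clusters 14 and 19 lie near 0 in wild type and at 5.66% and 4.55% in the knockout.

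Projection-neuron-like cells of the P0 knockout had lower transcripts of cholesterol synthesis and of deep layer markers. Of 16 cholesterol synthesis genes 15 lay below 0, with a median log2 ratio of -0.86, below all random lists, and the most abundant were Hmgcs1 (-1.14, -1.29 to -0.99), which makes the substrate of the rate-limiting step, Fdps (-0.19, -0.43 to 0.04), Fdft1 (-0.82, -1.07 to -0.58) and Cyp51 (-0.86, -1.12 to -0.61). Of 11 deep layer markers 9 lay below 0, with a median of -0.64 that was -0.30 as a mean over cells and -0.37 after thinning, and examples were Bcl11b (-0.53, -0.75 to -0.32) and Sox5 (-0.64, -0.94 to -0.34), whereas Tbr1 stood at -0.07 (-0.28 to 0.13). Immediate early genes had 8 of 11 members above 0 and a median of 0.25, with Egr1 at 0.52 (0.37 to 0.66), and Wnt pathway genes 13 of 15 and a median of 0.30, with Sfrp1 at 0.30 and Wnt7b at 0.36. Ribosomal protein genes had 84 of 100 members below 0 and a median of -0.29. The highest genes were Fos (1.02), an immediate early gene, Frat2 (0.88), a Wnt pathway activator, and the cell cycle genes Cdk6 (0.83) and Ccnd2 (0.77). The lowest were ENSMUSG00000121500 (-1.86), Gabra2 (-1.50), a GABA receptor subunit, Ncapd2 (-1.21), a condensin subunit, and Erdr1y (-1.14). Clusters 0 and 10 held 113 and 99 of the 389 wild-type cells and 95 and 75 of the 383 knockout cells, and cluster 1 held 115 and 150. Cluster 3, with Bcl11b and Tbr1 among its leading genes, held 46 and 53, so it was not smaller in the knockout. Cluster 17 held 16 and 10, at median depths of 9260.5 and 4782 counts, so its cells weighed more in the wild-type sum.

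Radial-glia-like and astrocyte-like cells of the P0 knockout had more transcripts of astrocyte markers and matrix proteoglycans and fewer of S phase genes. Of 14 astrocyte markers 12 lay above 0, with a median of 0.70, above all random lists, and examples were Apoe (1.01, 0.93 to 1.09), Slc1a2 (0.81, 0.72 to 0.91), a glutamate transporter, and Sparcl1 (0.55, 0.49 to 0.61). Of 18 neural proteoglycan and matrix genes 16 lay above 0, with a median of 0.38 that was 0.57 after thinning, including Ncan (0.69, 0.60 to 0.77), Bcan (0.69, 0.58 to 0.81) and Tnc (0.52, 0.44 to 0.60). Of 42 S phase genes 40 lay below 0, with a median of -0.41 that was -0.16 after thinning, such as Usp1 (-0.48, -0.73 to -0.23) and Pcna (-0.14, -0.27 to -0.00). The share of cells with 15 or more cycle counts after thinning was 31.6% (25.3 to 38.4) in wild type and 28.5% (23.6 to 33.7) in the knockout, with 0.258% and 0.262% in projection-neuron-like cells, and 76.2% and 78.0% without thinning. Unnamed cycling cluster 9, whose best score was for radial glia, lies outside the class and made up 2.30% of wild-type and 3.08% of knockout cells. All 13 measured mitochondrially encoded genes lay below 0, with a median of -0.55, and 92 of 96 ribosomal protein genes did, with a median of -0.42. Other genes with a longest transcript under 700 bases, looked at after the result was seen, were lower too, with medians of -0.21 here and -0.15 in projection-neuron-like cells. The highest genes there were Npc1 (1.75), which exports cholesterol from lysosomes, Slc30a10 (1.21), a manganese exporter, Tnfrsf19 (1.20) and Gfap (1.19), the astrocyte intermediate filament. The lowest were Mt2 (-1.40), a metallothionein, Slc38a2 (-1.29), an amino acid transporter, Hes1 (-1.24), a Notch target, and Gm8624 (-1.23; ENSMUSG00000121813). Cluster 6 held 161 of the 323 knockout and 71 of the 206 wild-type cells, so the class is a different mix in the 2 libraries.

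Inhibitory-neuron-like cells of the P0 knockout had lower cholesterol synthesis and synapse genes and higher S phase genes. Of 13 cholesterol synthesis genes 12 lay below 0, with a median of -1.04 that was -0.63 with classes from each cell's own score, led by Hmgcs1 (-1.38, -1.82 to -0.96) and Cyp51 (-1.04, -1.67 to -0.44). Of 16 synapse genes 14 lay below 0, with a median of -0.51 and Gria1 at -0.88 (-1.11 to -0.65). Of 29 S phase genes 26 lay above 0, with a median of 0.81, and Cdca7 stood at 1.15 (0.83 to 1.48) and Pcna at 0.78 (0.43 to 1.12). The highest genes were Cdon (2.36), a Hedgehog co-receptor, Cdk6 (2.06), Igfbp5 (2.01) and Notch1 (1.94). The lowest were Zfhx3 (-2.89), Foxp1 (-2.32), Neto1 (-2.30) and Prkce (-2.19), with 52.2% of the knockout Foxp1 counts in 1 cell. The class was a different mix here too, since clusters 4 and 15 held 57 and 35 of the 141 wild-type cells and 26 and 14 of the 106 knockout cells. In intermediate-progenitor-like cells, radial glia markers had 9 of 11 members above 0 and a median of 0.76, with Fabp7 at 0.76 (0.46 to 1.06), and upper layer markers had 10 of 11 below 0 and a median of -0.29. The highest genes there were Cenpf (4.80), of which 1 knockout cell held 58.9%, Nr2f2 (2.85), Mycn (1.81) and Pcyt1a (1.43). The lowest were ENSMUSG00000121500 (-2.40), Dnaaf9 (-1.38), 4833420G17Rik (-1.37) and Gm49980 (-1.22).

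In oligodendrocyte-lineage-like cells of the P0 knockout, 11 of 12 measured FGF and ERK pathway genes lay below 0, with a median of -0.45 at the 0.01th percentile, including the feedback inhibitors Spry2 (-0.83, -1.23 to -0.43) and Spry1 (-0.42, -0.81 to -0.02). BMP and TGF-beta pathway genes had 9 of 14 members below 0 and a median of -0.40, with Smad4 at -0.67 (-1.08 to -0.26) and Bmpr2 at -0.54 (-0.93 to -0.14). Notch pathway genes had 7 of 11 below 0 and a median of -0.26, with Hes5 at -0.77 (-0.96 to -0.58) and Notch1 at 0.03. These ratios rest on 52 wild-type and 150 knockout cells. Among 5286 genes measured in all 5 classes, 3 went the same way by at least 1 log2 unit throughout: AA465934, with a median of 3.40 over the classes, ENSMUSG00000121500, with -2.20, and Gm49980, with -1.53.

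**Figure D4:**
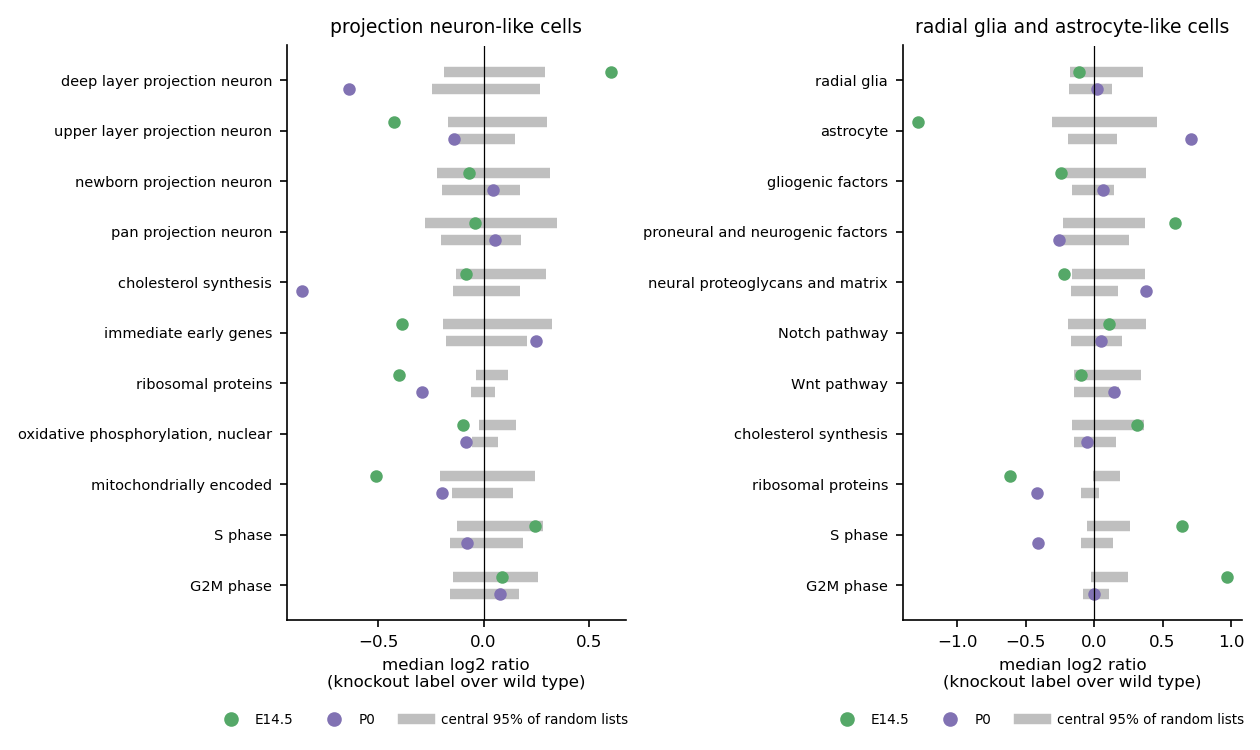
Median log2 ratio of knockout label over wild type (x axis) for gene lists (y axis) in projection-neuron-like cells on the left and radial-glia-like and astrocyte-like cells on the right, with points for E14.5 and P0 and grey bars for the central 95% of random lists. Deep layer markers lie at 0.60 at E14.5 and -0.64 at P0, and astrocyte markers at -1.29 and 0.70; Tsku contradicts the E14.5 label.

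Between E14.5 and P0 in wild type, projection-neuron-like cells went from deep layer to upper layer markers and radial-glia-like cells to astrocyte markers. Of 11 deep layer markers none lay above 0, with a median of -0.89 and Bcl11b at -2.69 (-2.84 to -2.55), and 11 of 13 upper layer markers did, with a median of 1.11 and Pou3f2 at 1.79 (1.69 to 1.89). In radial-glia-like and astrocyte-like cells all 12 astrocyte markers lay above 0, with a median of 2.55, and so did 15 of 16 cholesterol synthesis genes, with a median of 1.1, and 13 of 16 gliogenic factors, with a median of 1.26, led by Tnc (2.76, 2.53 to 2.99), whereas Nfib stood at -0.39. Proneural and neurogenic factors had 9 of 11 below 0 and a median of -1.14, with Sox11 at -1.12. The G2M list had 45 of 46 members below 0 and a median of -3.37 in inhibitory-neuron-like cells, and 41 of 42 and -3.69 in intermediate-progenitor-like cells. These falls depend on which dividing cells were named. Cycling clusters 5 and 20 of E14.5 are in these 2 classes, whereas cycling cluster 13 of P0, with 56 wild-type cells and near-equal scores for both, was left unnamed and lies outside them.

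The named genes follow the same classes. In projection-neuron-like cells the highest were Lypd6 (2.37), Zfhx4 (2.35), Fbxw7 (2.16), Plekha5 (2.08) and Atp1b1 (2.06). The lowest were Crym (-5.39), Nrp2 (-4.27), Vim (-4.00), Fezf2 (-3.94) and Kif26a (-3.33). In inhibitory-neuron-like cells the 4 highest were Mef2c (2.66), Wdfy1 (2.65), Sp8 (2.27) and Chl1 (2.13). The lowest, which rest on the naming of cycling clusters, were the mitotic genes Ckap2l (-6.19), Kif11 (-6.18), Cenpf (-5.63) and Mki67 (-5.61) together with Ttr, which had 0 counts at P0 and 78.6% of its E14.5 counts in 1 cell. In radial-glia-like and astrocyte-like cells the highest were the water channel gene Aqp4 (7.70), Hepacam (6.93), Olig1 (6.46), Trim9 (6.23) and Grm5, which had 0 counts at E14.5. The lowest were Nrp2 (-7.47), Cnmd (-7.28), Rspo3 (-6.78), Plac9 (-6.55) and Tmem132c (-6.30). The Olig1 ratio rests on naming as well. Cluster 9 of E14.5, with Olig1 and Olig2 among its leading genes and its best score for radial glia, was left unnamed and lies outside the class. In intermediate-progenitor-like cells the highest were Nos1, with 0 counts at E14.5, Osbpl6 (4.95), Lsamp (4.85), Slc8a1 (4.09) and Hs6st2 (3.93). The lowest, which rest on the naming of cycling clusters too, were the mitotic genes Mki67 (-7.96), Cenpf (-7.41), Nusap1 (-6.67), Top2a (-6.52) and Tpx2 (-6.30). In all 4 classes 15 genes went the same way by at least 1 log2 unit, 10 up and 5 down, with Nrp2 (-3.74), Igf2bp1 (-2.37), Onecut2 (-2.30), H1f10 (-1.84) and Rprm (-1.55) lower and Trim9 (3.04), Wdfy1 (2.5), low in E14.5 wild type alone, Atp1b1 (2.23), Tmem132b (1.97) and Unc5d (1.89) among the higher, as medians over the classes.

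Across genes, the ratio of knockout label over wild type at E14.5 had a Pearson correlation with the ratio at P0 of 0.14 in projection-neuron-like cells over 9597 genes, 0.08 in inhibitory-neuron-like cells, 0.05 in radial-glia-like and astrocyte-like cells and 0.13 in intermediate-progenitor-like cells. The age ratios of wild type and of the knockout labels, which share no library, correlated at 0.69, 0.52, 0.70 and 0.71 in the same order. Genes are not independent replicates, so no p-value is given, and Tsku contradicts the label of the E14.5 library in these comparisons.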

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

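All 5 tests on Tsku and the tests on depth and on the denominator of the oligodendrocyte share were chosen only after the result was seen.

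Unnamed clusters 14 and 19 of P0 stand out because they hold 5.66% and 4.55% of the knockout cells, against 1 and 2 wild-type cells, and enter no gene ratio within classes. Their cells do count in the denominator of every P0 share over all cells. Both express Prox1, at 569 and 510 CPM against 1.85 in projection-neuron-like cells of the same library, and Neurod1, at 1247 and 512 against 112, genes picked after their values had been seen. A wider dissection that included dentate gyrus may have brought these cells. Cluster 19 scored 0.84 for intermediate progenitors and 0.69 for thalamic cells, too close for a name, and a thalamic source was not tested. The dentate lineage list was read in clusters 14 and 19 pooled, against projection-neuron-like cells of the same library. Its median was -0.092 over the 6 of its 16 genes that were measured, inside the random range of -0.45 to 0.80. The rule that would have excluded dentate cells was withdrawn after the outcome, because an upper limit of 2.02 over resampled genes leaves a large rise possible. A pooled median also cannot speak for either cluster alone. For hippocampal pyramidal neurons among the knockout projection-neuron-like cells the list median was -0.19, inside the random range of -0.23 to 0.27, and the rule that would have excluded them was withdrawn too, because 4 genes lay above 0 and 6 below and a minority of such cells need not raise a median. A difference in dissection, a property of 1 library and an effect of genotype stay open for clusters 14 and 19.

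The oligodendrocyte-lineage share in the P0 knockout was weighed because it bears most directly on gliogenesis. Depth is argued against, since median counts per cell differed by 1.05 times and the log2 share ratio was 1.28 after thinning before clustering. The ratio was 1.23 without clusters 14 and 19, but removing cells that lie almost all in the knockout can only raise it, so this value decides nothing about the denominator. More medial pallial tissue in the knockout sample may contribute, as the medial pallium list, 2 of whose genes had been seen to lead cluster 19, had a median of 0.36 in radial-glia-like and astrocyte-like cells against a random range of -0.25 to 0.31, although its abundant members Zbtb20 (-0.12) and Emx2 (-0.21) lay below 0 and the list stood at percentile 49.1 of random lists in the oligodendrocyte-lineage-like cells themselves. An effect of genotype stays open and untested, with 1 animal on each side.

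Tsku in the library labelled E14.5 knockout, at 74 counts, goes against the label. Leakage between libraries is argued against, as the rate from Y-linked genes (2 counts against 5239 elsewhere) would bring at most 0.132 Tsku counts, and a swap of the E14.5 labels is argued against by 54 Tsku counts among all barcodes of the wild-type library. A transcript left by the allele is argued against by 0 counts in the P0 knockout where at least 23.5 would be expected, if both animals carry the same allele, and free RNA spread evenly over cells by a log2 ratio of 1.53 (0.35 to 2.93) between projection-neuron-like and inhibitory-neuron-like cells. A candidate explanation is an animal with a working Tsku allele, such as a heterozygote or a sample from outside the series, as the log2 ratio to wild type was -0.86 (-1.39 to -0.32). AA465934, at 34.1 CPM in this library, stood nearer the P0 knockout (54.4) than E14.5 and P0 wild type (6.09 and 6.64). ENSMUSG00000121500 did likewise, whereas Gm15772 was counted almost only in this library. These genes stood out by their ratios and do not decide between the 2 kinds of animal. An oddity stays unexplained, since no cell held more than 1 Tsku count, which was so for 3.84% of the 834 genes with 60 to 90 counts.

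Of 106 pairs of list and class compared at both ages, 8 had medians outside the random range in opposite directions, and these differences between the ages were not tested. Each is given as the P0 median minus the E14.5 median, and Tsku contradicts the label at E14.5. In projection-neuron-like cells the difference was 0.63 for immediate early genes, from -0.39 to 0.25. Deep layer markers in the same class differed by -1.24, from 0.60 to -0.64. S phase genes in inhibitory-neuron-like cells differed by 1.14, from -0.33 to 0.81. Cholesterol synthesis genes in that class differed by -1.38, from 0.34 to -1.04. In radial-glia-like and astrocyte-like cells S phase genes differed by -1.05, from 0.64 to -0.41. Proneural and neurogenic factors there differed by -0.85, from 0.59 to -0.25. Neural proteoglycans and matrix genes there differed by 0.60, from -0.22 to 0.38. Astrocyte markers there differed by 1.99, from -1.29 to 0.70.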

How the results depend on the processing

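The tests with a threshold of 15 cycle counts, with 3 classes alone and with unnamed clusters placed in their best class were chosen only after the result was seen. Of 245 values of 36 results under alternatives, 216 stayed within their counting interval (within 0.1 for correlations), 25 moved beyond it and 4 changed sign from an interval that excluded 0. Of 886 values of 181 single genes 827 stayed, 58 moved and 1 changed sign in that way. The alternative count minimums decide only whether a gene is measured and leave its ratio unchanged. Single gene values under them stayed by construction, so the 827 overstate how stable single genes were. The cycling shares among the other results count cells with 2 or more cycle counts, which nearly all cells had. Their values with 1 count or without thinning lay close to the main value by construction, so the 216 overstate stability as well. Among values of results and of single genes that stayed or moved, 6 and 1 changed sign where the interval held 0. The share ratio of E14.5 inhibitory neurons kept its sign in 10 of 12 alternatives, with a lowest value of -0.063. The cause was not tested for any value below.

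The P0 intermediate progenitor ratio changed sign to 0.40 with 4 libraries together, 0.15 with the stricter filter, 0.83 at resolution 2 and 0.012 with unnamed clusters placed, and ENSMUSG00000121307 in E14.5 radial glia to -0.15 after thinning. The P0 projection neuron ratio moved to -0.18 with 4 libraries together, -0.72 with own marker scores, -0.23 among 3 classes alone and -0.20 with unnamed clusters placed. The E14.5 one moved to -0.52 with all barcodes. With each library alone the ratios moved to 1.40 for E14.5 inhibitory neurons, 2.06 for E14.5 radial glia, 0.57 for the P0 oligodendrocyte lineage and 0.95 for P0 radial glia.

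The E14.5 radial glia G2M median moved to 1.00 with TMM, 0.62 after thinning, 0.67 with doublets kept, 0.71 as a mean over cells and 0.66 with own scores, and the S phase median to 0.68 with TMM and 0.71 with own scores. Over all its alternatives that S phase median lay between 0.46 and 0.71. After thinning the P0 radial glia medians moved to -0.16 for S phase, 0.50 for astrocyte markers and 0.57 for proteoglycans. P0 deep layer markers moved to -0.37 after thinning, -0.30 as a mean over cells and -0.37 with own scores, and cholesterol synthesis in P0 inhibitory neurons to -0.63 with own scores. E14.5 ribosomal proteins in projection neurons moved to -0.90 with no count filter. The log2 ratio of the E14.5 radial glia cycling share moved from 0.02 to 0.52 with 15 counts.

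The P0 oligodendrocyte ratio kept its sign in 12 of 12 alternatives, from 0.57 to 1.28, and the P0 cholesterol median in projection neurons in 8 of 8, from -0.88 to -0.77.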

Other observations

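The test of short transcripts was chosen only after the result was seen, and the rules for calling 5 tests decided were changed after their outcomes were known. These were the tests on the age of the E14.5 embryo and on the genes around Tsku here, and those on the dentate list, the hippocampal pyramidal list and the denominator above. The rule on a later stage at P0 was changed as well, and its outcome is open under both versions.

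In oligodendrocyte-lineage-like cells of the P0 knockout, synapse genes had 12 of 15 members above 0 and a median log2 ratio of 0.46, with Nlgn1 at 0.77 and abundant Gria2 at -0.15, while cholesterol synthesis genes had 10 of 15 below 0 and a median of -0.37, with Idi1 at -0.46 and abundant Hmgcs1 at 0.02. Inhibitory-neuron-like cells of the same library had higher gliogenic factors, with 5 of 6 above 0, a median of 0.74 and Nfia at 0.93. P0 clusters 14 and 19 differed from each other, with Mki67 at 6.23 and 228 CPM and Zic1 at 68.5 and 438, against 1.85 and 13.9 in projection-neuron-like cells.

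AA465934 and ENSMUSG00000121500 separated both libraries labelled knockout from both wild-type libraries. Over all cells AA465934 stood at 34.1 and 54.4 CPM in the libraries labelled knockout and at 6.09 and 6.64 in wild type, and ENSMUSG00000121500 at 31.9 and 39.7 against 189 and 173. Genetic background carried along with the Tsku locus could cause such differences, and the 40 nearest measured genes around Tsku had a median absolute log2 ratio of 0.233 in P0 projection-neuron-like cells, inside the random range of 0.146 to 0.303. AA465934 lies on another chromosome than Tsku. The rule set beforehand would have excluded a linked background, but an upper limit of 0.381 over resampled genes exceeds the random range, so the test leaves it open.

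A shift in developmental stage might produce list differences of opposite sign at the 2 ages. For a younger embryo in the library labelled E14.5 knockout, the ratio in projection-neuron-like cells correlated across genes at 0.046 with the age ratio of wild type and at -0.50 with the age ratio of the knockout labels. The rule set beforehand would have excluded it, but each age ratio shares a library with the label ratio, which pushes 1 correlation up and the other down, so it stays open. For a later stage in the P0 knockout, the same correlations of the P0 ratio in radial-glia-like and astrocyte-like cells were 0.035 and 0.34. Here the shared library pushes the first value down and the second up. The first stayed positive but short of the level set for a later stage, so that explanation stays open. Genes are not independent replicates.

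Lower ribosomal protein counts in the library labelled E14.5 knockout may reflect in part a bias by transcript length. In projection-neuron-like cells 123 other genes with a longest transcript under 700 bases had a median log2 ratio of -0.21, below the random range of -0.02 to 0.16. Such genes were lower in the P0 knockout too, with a median of -0.15 in the same class. Length alone as the whole cause is argued against, because random genes matched on principal coding transcript length had a median of 0.036 (-0.078 to 0.13) where ribosomal protein genes had -0.40, a length measure added after the first had been seen to overstate ribosomal lengths. Those random genes were not matched on expression, so a length bias that depends on expression stays open.

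More free RNA in the library labelled E14.5 knockout may place projection neuron transcripts in other classes. In endothelial, microglial, meningeal and choroid plexus cells, which should lack them, the summed pan projection neuron list stood at 437 CPM against 222 in wild type, a log2 ratio of 0.98 (0.72 to 1.24). Doublets that were not called could add to this and were not separated from it. Median depths in that library and in wild type were 6198.5 and 12006 counts in endothelial-like and 2813.5 and 7185 in microglia-like cells. They were 4009 and 7559 in meningeal-fibroblast-like and 3970.5 and 8734 in choroid-plexus-like cells. A like amount of free RNA per cell could weigh more in such shallow cells, so the ratio does not separate more free RNA from less RNA per cell.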
